A study of Drosophila mojavensis with 14 samples.

How the data were processed

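Lower reproductive tracts of Drosophila mojavensis females were profiled on 1-colour NimbleGen expression arrays with Cy3 label, per the labels. Females were virgin, or had copulated with males of their own species (conspecific) or with Drosophila arizonae males (heterospecific), and mated tracts were taken 15 min, 2 h or 6 h after copulation. Flies were aged 10 to 12 days, each mated female was put in a vial with 2 males, and each sample pooled 20 to 25 tracts. The 7 groups held 2 samples each, which the labels describe as biological replicates, so 14 arrays were analysed. RNA was amplified before labelling, per the labels' protocols.

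The deposited files held 1 perfect-match intensity per probe, extracted with NimbleScan 2.4.67, per the file headers. The highest mismatch value was 0. The submitters' processing notes name RMA, but the deposited value table was the same as the raw probe intensity on every array (0 probes differed), so no normalized intensity from the authors was used. Each array carried 71998 probes for 14519 transcripts, of which 13925 had 5 probes and 592 had 4. No probe was named as a random or control probe. Transcripts were named by a GI number (14471) or a symbol (48). The reference table of gene names matched 0 of these names, so GI numbers are given as in the files, and which genes they stand for was not analysed here. For the same reason the 23 gene lists fixed before the data were examined held 1 member on the array, cbt, and none was tested.

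Probe intensities were corrected with limma's normexp method (offset 50), quantile normalized between arrays, put on the log2 scale and summarised per transcript by median polish, with R 4.3.3 and limma 3.58.1. All 14519 transcripts were kept, because the filter planned for dim transcripts needed control probes. The offset understates the change of dim transcripts. With no control probes, a background limit was set after the data were seen: the mode of an array's transcript values plus 2 SDs of the values left of the mode. A transcript below that limit on both arrays of a group is called not above background there, and its change is then given as at least N-fold. Where a refit of such a transcript has no bound, its fitted log2 value is given only to show how far it moved. That bound sets the mean of the brighter group against the dim group's mean of, per array, the higher of the limit and the measured value.

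Groups were compared with limma, with 1 mean per group over all 14 arrays, so that the groups shared 1 estimate of the spread (7 residual and 3.56 prior degrees of freedom). Tests were 2-sided, and adjusted p-values are Benjamini-Hochberg values over all transcripts, with a threshold of 0.05. The median SE of a log2 difference between groups of 2 arrays was 0.224, and the number of arrays limits the precision. Tested on simulated data for conspecific against virgin at 15 min over 14519 transcripts, the fit recovered 50.7% of transcripts changed by 1 on the log2 scale, 86.6% of those changed by 2 and 100% of those changed by 3, and it called 9 unchanged transcripts. The simulation changed 67, 67 and 66 transcripts at once, which eases the adjusted threshold, and its noise was independent between transcripts. The real comparison called only 9, so its recovery can be lower. Name classes were tested with limma's camera at a preset correlation of 0.01 and with an estimated correlation.

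The rule for named transcripts, fixed before the data were examined, took in each of the 9 comparisons at a single time up to 5 symbol-named transcripts with the largest rise and 5 with the largest fall and, because the files pair GI numbers with no names, the 2 GI numbers that rose most and the 2 that fell most. They had to pass the threshold, to have both arrays of 1 group above or below both of the other, and to be above background in at least 1 of the groups. The same choice was made for the comparisons over several times, without the separation of arrays. Other transcripts named in the text were chosen after their values were seen. The classes Acp, Tes and moj, taken from the start of the probe names, were also chosen after the data were seen, as was the comparison of 6 h with 15 min over both mating types and that of each mating type, averaged over the 3 times, with virgin.

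Each array lay on a slide of its own. Probe values were read from the array images on 2 days, per the file headers, called extraction days here (they are not days of RNA extraction): on day 1 both heterospecific arrays at 2 h, both at 6 h, heterospecific 15 min replicate 1 and conspecific 6 h replicate 2, and on day 2 the other 8. Alternatives fixed before the data were examined were a normexp offset of 0, no background correction, median scaling, cyclic loess, the mean of the probes, the deposited value table, eBayes with trend and robust settings, a fit of the compared groups alone, a minimum change of 2-fold, the replicate number or the extraction day as a block, array weights, and leaving out each array. A filter for transcripts above background on every array was also planned, with a limit set only after the data were seen. A filter for transcripts above it in 1 group, the probe slope as a covariate, fits within each day, and a fit without 4 arrays of low raw upper quartile were added after the data were seen.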

Results

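The arrays measured RNA in the lower reproductive tract of virgin and mated D. mojavensis females, to describe transcript changes after mating and whether they depend on the species of the male. Each of the 7 groups had 2 arrays. The raw upper quartile of probe intensity was 943 on conspecific 15 min replicate 2, 1056 on virgin replicate 2, 1183 on conspecific 6 h replicate 1 and 1413 on conspecific 2 h replicate 1, and above 1500 on the other 10 arrays, and these 4 are called the dim arrays here. Fits without these 4 kept a lone array in the virgin and in each conspecific group, so their spread came from the heterospecific groups alone. Leaving out replicate 1 of virgin or of conspecific 15 min leaves a dim array alone in its group. The same holds for replicate 2 of conspecific 2 h or 6 h. The first principal component of the arrays held 44.7% of the variance. It followed the slope of probe intensity along the transcript, a sign of RNA or amplification quality, with Pearson's r of 0.821 (permutation p = 0.00022, adjusted 0.00044) and Spearman's rho of 0.802 (permutation p = 0.00089, adjusted 0.00089) over 14 arrays and 2 tests. Without the 2 arrays farthest from the median slope, r was 0.729. It was 0.948 over the 6 arrays whose images were read on day 1 and 0.784 over the 8 of day 2.

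**Figure D1:**
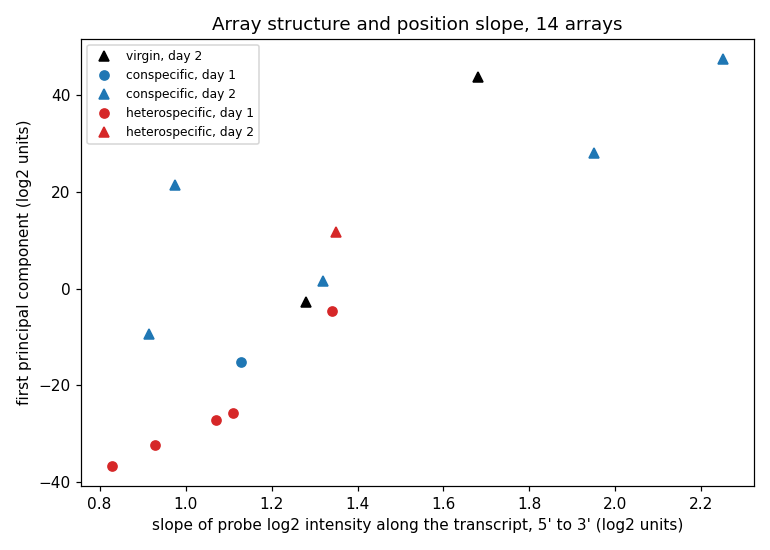
First principal component of the 14 arrays (vertical axis, log2 units) against each array's slope of probe log2 intensity along the transcript (horizontal axis, log2 units), with colour for virgin, conspecific or heterospecific and marker shape for extraction day. Arrays with a steeper slope lie higher, with r of 0.821.

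Conspecific mating was followed by very large rises of a few transcripts that were dim in virgins. GI14761 rose by 5.48 on the log2 scale at 15 min (44.5-fold, SE 0.30, limma adjusted p = 3.24e-05), from 7.70 ± 0.53 in virgins to 13.17 ± 0.33 (SD, n = 2), and GI20303 rose by 5.44 (43.5-fold, SE 0.40, adjusted p = 0.000342), from 8.01 ± 0.05 to 13.45 ± 0.05. Both were still higher at 2 h, by 5.20 and 5.02, and at 6 h, by 3.86 and 4.13, where GI20303 lay at 12.93 and 11.34 on the 2 arrays and its change was 3.33 or 4.92 without replicate 1 or 2. The other transcripts higher at 2 h, named after their values were seen, were GI10632, GI17635 and GI17134, by 2.73, 2.55 and 2.09. GI12810 fell by 1.28 at 15 min (adjusted p = 0.0247) and by 1.27 at 6 h (adjusted p = 0.0483), and GI24422 fell by 1.23 at 6 h (adjusted p = 0.0264).

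In all, 8 transcripts were higher and 1 lower than in virgins at 15 min, 5 higher and 0 lower at 2 h, and 2 higher and 2 lower at 6 h. With median scaling the counts at 15 min and 6 h were 5 higher and 0 lower and 2 and 0, and with cyclic loess 6 and 0 and 2 and 1. At 15 min, 2 h and 6 h, 517, 522 and 1168 of 14519 transcripts had an unadjusted limma p under 0.05, where chance gives 726. All 5 transcripts called at 2 h were also called at 15 min. Fits of the compared groups alone called 1, 1 and 0 transcripts. The 6 h count was 30 (25 higher and 5 lower) without conspecific 6 h replicate 1 and 138 (117 higher and 21 lower) without the 4 dim arrays. It was 2 without any 1 of the arrays at conspecific 15 min or 2 h or heterospecific 15 min or 2 h. Without conspecific 2 h replicate 1 or virgin replicate 2 the 2 h count was 2, and without the 4 dim arrays it was 3. The 6 h call of GI12810 was lost without any 1 of the 14 arrays (adjusted p of 0.0568 to 0.168), that of GI24422 without any 1 of 12, all but the conspecific 6 h arrays (0.054 to 0.104), and the 15 min call of GI12810 without any 1 of 11 (0.0513 to 0.408). With the day as a block the change of GI12810 at 6 h had an adjusted p of 0.0768, and with median scaling the adjusted p of GI12810 at both times and of GI24422 was 1. Both virgin arrays and all conspecific arrays at 15 min and 2 h had their images read on day 2, where fits of that day alone called 2, 2 and 1 transcripts, the last with 1 conspecific array.

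**Figure D2:**
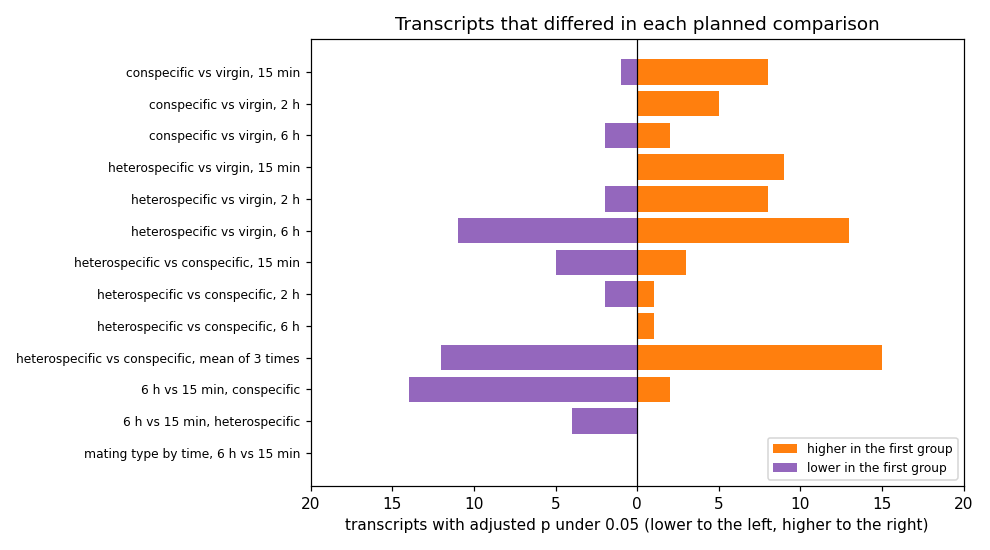
Number of transcripts with a limma adjusted p under 0.05 in each of 13 planned comparisons, those lower in the first group drawn to the left and those higher to the right of 0. The largest count is 27, for heterospecific against conspecific over the 3 times, and the comparison of mating types over time has 0.

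After heterospecific mating GI20303 rose as well, by 5.91 at 15 min (60.0-fold, SE 0.40, adjusted p = 0.0003), 5.46 at 2 h and 5.24 at 6 h. Acp2, whose name follows the usual naming of Drosophila accessory gland protein genes, was not above background in virgins (6.82 ± 0.20) and at least 10.8-fold higher at 15 min (SE of the log2 change 0.49, adjusted p = 0.0142), with 9.94 on replicate 1 and 12.00 on replicate 2. GI18622 was at least 8.23-fold higher at 15 min, with 9.60 on replicate 1 and 11.56 on replicate 2. Without replicate 1 or 2 of that group the fitted log2 change was 5.18 or 3.12 for Acp2, from 4.15, and 4.92 or 2.95 for GI18622, from 3.94. These fitted values rest on virgin levels not above background and show only how far the change moved. GI23890 was at least 7.15-fold higher at 2 h and 5.13-fold at 6 h. GI15007 fell by 2.04 at 2 h and by 2.82 at 6 h (adjusted p = 0.000705), and GI14996 fell by 1.88 at 2 h (adjusted p = 0.0108). GI15792 fell by 2.85 at 6 h (adjusted p = 0.0192).

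The counts were 9 higher and 0 lower at 15 min, 8 and 2 at 2 h, and 13 and 11 at 6 h. An unadjusted limma p under 0.05 was reached by 406, 2195 and 2583 of 14519 transcripts, where chance gives 726. Over the 3 times 8 transcripts were higher than in virgins after conspecific mating and 19 after heterospecific mating, with GI14761, GI17635 and GI20303 in both, and 10 of the 24 different transcripts were not above background in virgins. With median scaling 6 were higher and 0 lower at 2 h and 9 and 2 at 6 h. Cyclic loess gave 4 and 2 at 2 h and 17 and 21 at 6 h. The dim virgin replicate 2 was the only virgin array once replicate 1 was left out. Without virgin replicate 2 the counts of calls were 4, 1 and 7, without virgin replicate 1 they were 5, 326 (132 higher and 194 lower) and 389, and without the 4 dim arrays 3, 4 and 79. The 15 min count was 33 without heterospecific 15 min replicate 1. The 2 h count was 1 without either array of that group, 19 without either heterospecific 15 min array, 17 without either conspecific 6 h array, 6 without either conspecific 2 h array and 5 without either heterospecific 6 h array. The 6 h count was 6 (2 higher and 4 lower) or 4 (1 and 3) without replicate 1 or 2 of that group and 11 (4 higher and 7 lower) without either heterospecific 2 h array. Without virgin replicate 1 or 2 the adjusted p of Acp2 at 15 min was 0.0792 or 0.0899, and that of GI18622 0.0829 or 0.0899. At 2 h the calls of GI23890, GI15007 and GI14996 were lost without either heterospecific 2 h array or virgin replicate 2 (adjusted p of 0.0929 to 0.39). At 6 h those of GI23890 and GI15792 were lost without any 1 of the heterospecific 2 h and 6 h arrays or virgin replicate 2 (0.0521 to 0.363). Heterospecific arrays at 2 h and 6 h were all read on day 1 and virgins on day 2, and with the day as a block the counts at 2 h and 6 h were 5 and 7. In that fit the calls of GI15007 and GI14996 at 2 h (-2.04 and -2.15, adjusted p of 0.172 and 0.057) and of GI15792 at 6 h (-2.25, adjusted p = 0.388) were lost. The log2 change of GI20303 was then 6.39 at 2 h and 6.17 at 6 h. For GI23890, not above background in virgins, the fitted value was 3.79 and 3.31, from 2.95 and 2.47. With median scaling GI15007 and GI14996 at 2 h were at -1.37 and -1.19 (adjusted p of 0.252 and 0.297), and without the 4 dim arrays the adjusted p of Acp2 and GI18622 at 15 min was 0.22. On day 2 alone the 15 min count was 15, but only 1 heterospecific array of that time lay there. The spread came from the 3 groups with 2 arrays on that day, and a lone array was assumed to vary like them.

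**Figure D3:**
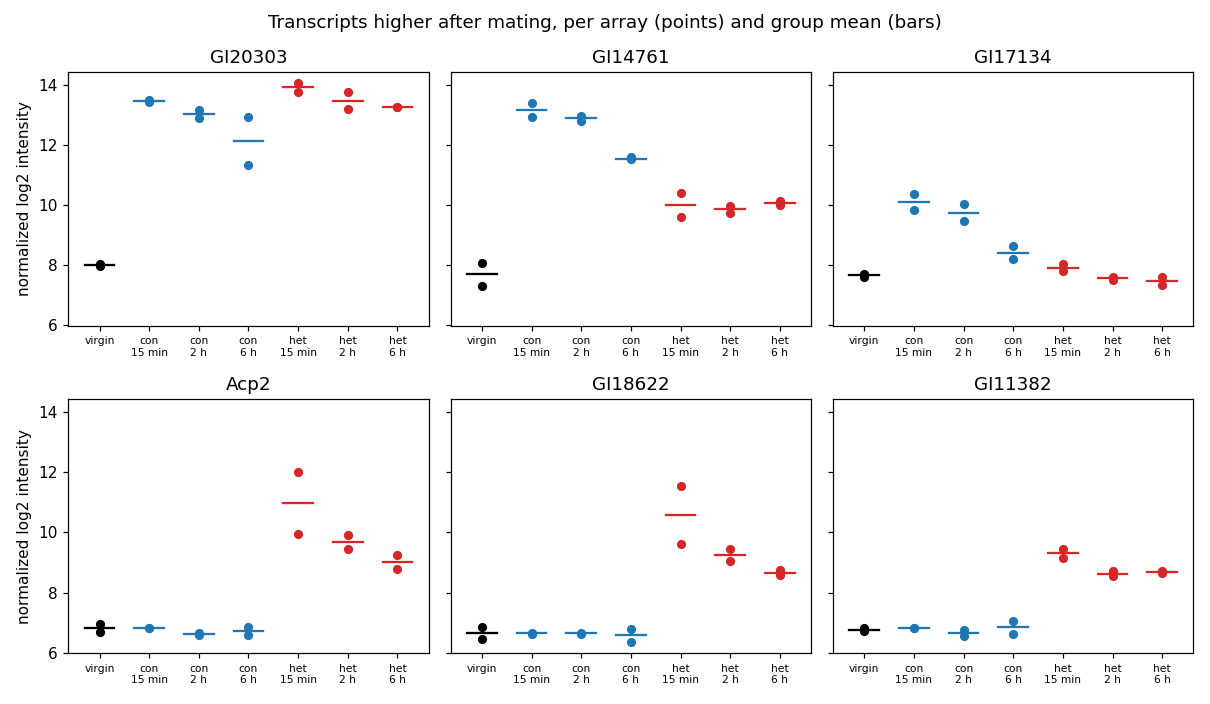
Normalized log2 intensity (vertical axis) of 6 transcripts on each array (points) with group means (bars), for virgin, conspecific (con) and heterospecific (het) groups. Acp2, GI18622 and GI11382 are above background in heterospecific groups and in no virgin or conspecific group, and the 2 heterospecific 15 min arrays of Acp2 lie at 9.94 and 12.00.

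At the threshold, the response to the species of the male differed directly for a small number of transcripts. Over the 3 times, however, 2870 of 14519 had an unadjusted limma p under 0.05, where chance gives 726. At 15 min, 2 h and 6 h these were 478, 1136 and 1428. Mating type, extraction day or array structure could each give such a broad excess, and they were not told apart for it. Averaged over the 3 times, Acp2 was at least 5.41-fold higher after heterospecific than after conspecific mating (SE of the log2 difference 0.28, limma adjusted p = 0.0013), GI18622 at least 4.11-fold, and GI17833 was higher by 2.18. GI14761 was lower by a log2 difference of -2.55 (SE 0.17, adjusted p = 0.000143) and GI17134 of -1.78 (SE 0.14, adjusted p = 0.000489). GI11382, not above background in virgins or after conspecific mating, was at least 3.43-fold higher at 15 min, 2.31-fold at 2 h and 2.37-fold at 6 h, and was the only transcript called at each of the 3 times in this fit. At 15 min GI14761 differed by -3.15 (adjusted p = 0.00277) and GI10632 by -2.31 (adjusted p = 0.0331).

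Of the 4 transcripts named Acp, only Acp2 passed the test over all transcripts, while 2 rose at 15 min adjusted over the list alone. Between mating types by that adjustment, 1 was higher and 1 lower at 6 h, and 2 were higher and 1 lower over the 3 times. At 15 min after heterospecific mating Acp11 was at least 2.49-fold higher than in virgins (adjusted p = 0.157 over all transcripts), the log2 change of Acp7 was -0.08, and Acp48 was not above background in any group, so their median of 1.07 lay near none of the 4 (camera adjusted p = 0.000121, and adjusted p = 0.0202 with an estimated correlation) and the median after conspecific mating was 0.10 (camera adjusted p = 0.57). Between mating types at 15 min the median difference was 0.86 (camera adjusted p = 0.0023, and adjusted p = 0.0512 with an estimated correlation), and without conspecific 15 min replicate 1 its adjusted p was 0.0862. Of 25 transcripts named Tes and 6 named moj, 0 passed in the comparisons of mating types over all transcripts. However, 11 of the 25 were not above background in any group. Adjusted over the list alone, 1 Tes transcript was higher over the 3 times. The median of all 25 Tes transcripts over the 3 times was -0.08 (camera adjusted p = 0.47), and the moj median of 0.23 over the 3 times (camera adjusted p = 0.0135) had an adjusted p of 0.165 with an estimated correlation.

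The comparison of mating types called 3 higher and 5 lower at 15 min, 1 and 2 at 2 h, 1 and 0 at 6 h, and 15 and 12 over the 3 times. With median scaling they were 6 and 2 at 15 min, 2 and 2 at 2 h, 0 at 6 h and 8 and 4 over the 3 times, and with cyclic loess 0 at 6 h. Fits of the compared groups alone called 0 at each single time. The count over the 3 times was 10 (8 higher, 2 lower) with the extraction day as a block, and 9 (2 higher, 7 lower) without the 4 dim arrays. Without replicate 1 or 2 it was 15 or 11 for conspecific 15 min, 12 or 10 for conspecific 2 h, 16 for either conspecific 6 h array, 8 for either heterospecific 2 h array, and 12 or 9 for heterospecific 6 h. At 15 min it was 35 (30 higher and 5 lower) without heterospecific 15 min replicate 1, and 5 or 3 without conspecific 15 min replicate 1 or 2. At 2 h it was 0 without any 1 of the 4 arrays at that time and 9 (7 higher and 2 lower) without either heterospecific 15 min array. At 6 h it was 39 (2 higher and 37 lower) without the 4 dim arrays and 13 (2 and 11) without conspecific 6 h replicate 1. It was 3 without either heterospecific 15 min array, and 0 without conspecific 6 h replicate 2 or any 1 of the heterospecific 2 h and 6 h arrays. Without conspecific 15 min replicate 1 or 2 the adjusted p of Acp2 and GI18622 at 15 min was 0.129 or 0.141. GI10632 lost its call without any 1 of 9 arrays (0.0546 to 0.468), with the day as a block (0.101), with median scaling (0.0698) and with the probe slope as a covariate (0.0859). GI11382 lost its call at 2 h without any 1 of the 4 arrays at that time (0.0621 to 0.129), and at 6 h without any 1 of 5 arrays (0.0534 to 0.375), and with median scaling at both times (0.0813 and 0.369). GI17833 over the 3 times lost its call without replicate 2 of heterospecific 2 h (0.0564) or 6 h (0.0512). Within a day, 10 transcripts (9 higher and 1 lower) were called at 15 min on day 2, where only 1 heterospecific array of that time lay, and 94 (17 higher and 77 lower) at 6 h on day 1, where only 1 conspecific array lay. With the day as a block the counts were 15 (11 higher and 4 lower) at 15 min, 4 (3 higher and 1 lower) at 2 h and 1 at 6 h. Over the 3 times the fitted log2 difference was then 2.98 for GI17833 (adjusted p = 0.00202), from 2.18. For Acp2, not above background after conspecific mating, the fitted value was 3.78, from 3.17. Without the 4 dim arrays the adjusted p of Acp2 and GI17833 over the 3 times was 0.0503 and that of GI18622 0.0506.

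Between 15 min and 6 h, GI15007 and GI14996 fell after both matings. GI15007 fell by 2.17 after conspecific mating (SE 0.22, limma adjusted p = 0.00829) and by 2.89 after heterospecific mating (adjusted p = 0.000672), and GI14996 fell by 2.69 after heterospecific mating (adjusted p = 0.000672). After conspecific mating GI14198 fell by 2.10 (adjusted p = 0.0396), while GI22156 rose by 2.42 and GI23861 by 1.48 (adjusted p = 0.0409 for both). Without any 1 of 8, 8 and 10 arrays these 3 calls were lost, with adjusted p-values up to 0.305, and without conspecific 15 min replicate 2 that of GI15007 after conspecific mating was 0.0864. With median scaling these 4 had adjusted p-values of 0.149 to 0.533, with the probe slope as a covariate of 0.0654 to 0.152, and with median scaling that of GI14996 after heterospecific mating was 0.0922. Over both mating types, a comparison added after the data were seen, GI16419 rose by 2.77 (SE 0.36, adjusted p = 0.0128) and GI11033 by 2.26. Xdh, the gene of xanthine dehydrogenase, fell by 1.58 (SE 0.27, adjusted p = 0.0214), Tes134 fell by 1.27 (adjusted p = 0.048), and Tes131, not above background at 6 h, was at least 1.43-fold lower (adjusted p = 0.0428). Tes134 lost its call without any 1 of 11 arrays (0.0527 to 0.225) and Tes131 without any 1 of 8 (0.0785 to 0.17).

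The tests called 2 higher and 14 lower at 6 h after conspecific mating and 0 and 4 after heterospecific mating, and all 4 were among the 16. With median scaling the counts were 0 and 2, and with cyclic loess 20 and 11, the latter with 3 higher and 8 lower. With the day as a block they were 110 and 5. Without 1 array the conspecific count was 0 for conspecific 15 min replicate 2, 38 for its replicate 1, 8 for conspecific 6 h replicate 2 or either heterospecific 15 min array, 7 for either heterospecific 2 h array, 50 for either virgin array and 23 (15 higher and 8 lower) for conspecific 6 h replicate 1. The heterospecific count was 32 or 2 without heterospecific 15 min replicate 1 or 2, 2 without heterospecific 6 h replicate 2 and 8 without either conspecific 2 h array. For the difference of these changes between mating types limma called 0 transcripts, with 466 at an unadjusted p under 0.05, where chance gives 726, and a lowest adjusted p of 0.139, while without heterospecific 15 min replicate 1 the count was 16. Over both mating types 143 were higher and 186 lower, but the balance of directions turned with cyclic loess (233 and 230) and without conspecific 6 h replicate 1 (226 and 125). The count of 329 was unstable: 11 with median scaling, 19 with the probe slope as a covariate, 80 with the day as a block, 8 without heterospecific 6 h replicate 2, 38 without conspecific 15 min replicate 2 and 722 (397 higher and 325 lower) without its replicate 1. It was 99 without conspecific 6 h replicate 2, 89 or 66 without heterospecific 15 min replicate 1 or 2, 94 without either heterospecific 2 h array, 117 without heterospecific 6 h replicate 1 and 824 (519 higher and 305 lower) without the 4 dim arrays. The fit without those 4 kept a lone array in the virgin and in each conspecific group, so its spread came from the heterospecific groups alone. Leaving out conspecific 15 min replicate 1 kept only the dim replicate 2 of that group. Without heterospecific 6 h replicate 2 the adjusted p of GI16419 and GI11033 was 0.0818, and that of Xdh 0.122. Xdh also lost its call without conspecific 15 min replicate 2 (0.0694), conspecific 6 h replicate 2 (0.055) or heterospecific 15 min replicate 1 (0.0696) or 2 (0.0646). With the day as a block the adjusted p was 0.0665 for Xdh, 0.128 for Tes134 and 0.15 for Tes131. With the probe slope as a covariate the log2 change was 2.02 for GI16419 (0.0198), from 2.77, 1.72 for GI11033 (0.0568), -0.99 for Xdh (0.0568), -0.68 for Tes134 (0.226) and -0.52 for Tes131 (0.279). With median scaling the adjusted p was 0.082 for Xdh, 0.148 for Tes134 and 0.21 for Tes131. GI15007 and GI14996 over both mating types were past the threshold in 28 of 29 refits each, all but that of the deposited value table.

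**Figure D4:**
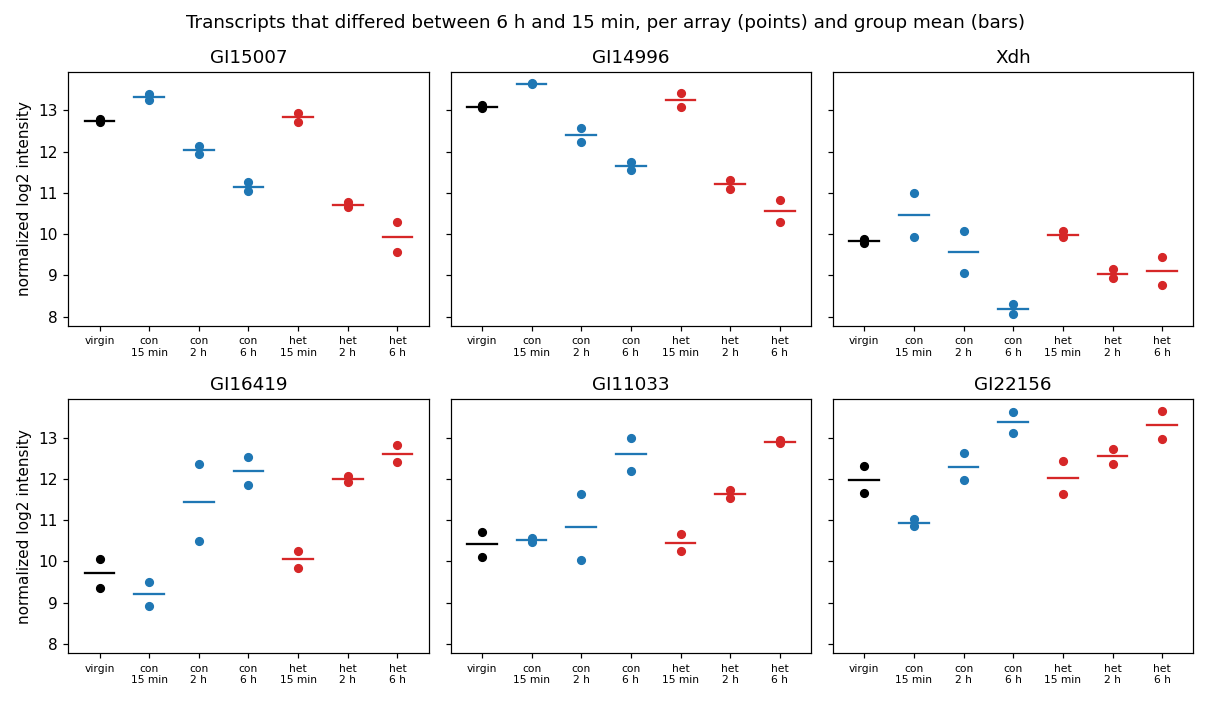
Normalized log2 intensity (vertical axis) of 6 transcripts on each array (points) with group means (bars) in virgin, conspecific (con) and heterospecific (het) groups. GI15007 and GI14996 are lower at 6 h than at 15 min after both matings, and GI16419 and GI11033 are higher.

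Changes from virgin correlated between the 2 matings, over transcripts, which are not independent, at r of 0.538 at 15 min, 0.615 at 2 h and 0.595 at 6 h. Unchanged groups set against the same virgin arrays gave 0.5 (0.474 to 0.524) in 100 simulations. All simulations here drew the noise of each transcript independently, while in the data 1 component held 44.7% of the variance. Their ranges can thus be too narrow, and they do not show r to be above that of unchanged groups. The 2 comparisons shared 3, 3 and 2 transcripts called higher, where independent lists give 0.00496, 0.00276 and 0.00179, and 1 called lower at 6 h, where they give 0.00152. Lists of the same sizes from unchanged groups against the same virgin arrays shared 1.05, 0.67 and 0.53 higher on average and up to 3, 3 and 2, and 0.56 lower at 6 h and up to 2, in 100 simulations, so none of these overlaps was above the highest simulated. Those lists were the top-ranked transcripts, which did not need to pass the threshold. They therefore do not decide whether overlaps of called transcripts come from the shared virgin arrays. The covariance was 0.0486, 0.0861 and 0.101 beside a simulated 0.0464. Of transcripts called in either comparison, 93.3%, 83.3% and 100% had the same sign, where those simulations gave 93.0%, 93.1% and 92.2%. The 2 shared virgin arrays were too few to split, so part of the agreement can come from them. The simulated 0.5 applies to 2 arrays in every group and no block. It depends on the number of arrays per group and was not redone for the refits below, so they cannot be set against it. With the day as a block r was 0.42, 0.424 and 0.696, and on day 2 alone 0.418 at 15 min. Without virgin replicate 1 r was 0.832, 0.861 and 0.825, and without virgin replicate 2 it was 0.407 at 2 h. It was 0.212 at 15 min without conspecific 15 min replicate 1, 0.203 at 2 h without conspecific 2 h replicate 2 and 0.183 at 6 h without conspecific 6 h replicate 2.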

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

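The tests of extraction day, of probe mismatch for both subsets of transcripts lower after heterospecific mating, of the direction of change of raised transcripts, those raised at single times included, and of drift of the scale, of the probe slope for the change with time, and both tests of the first principal component were chosen after the results were seen. The following transcripts stood out because their response differed between the 2 mating types by limma's test of the difference itself. At 15 min the log2 difference, heterospecific minus conspecific, was 4.14 for Acp2, 3.94 for GI18622, 2.47 for GI11382, -1.73 for GI11600, -2.19 for GI17134, -2.21 for GI20788, -2.31 for GI10632 and -3.15 for GI14761. At 2 h it was 1.97 for GI11382, -2.18 for GI17134 and -3.03 for GI14761, and at 6 h 1.85 for GI11382. For Acp2, GI18622 and GI11382 the conspecific level was not above background, and for GI11600 the heterospecific one, so their differences are fitted values. Their bounds at 15 min were at least 11-fold, 8.37-fold and 3.43-fold higher, and 3.07-fold lower. For GI11382 the bound was at least 2.31-fold at 2 h and 2.37-fold at 6 h. Without heterospecific 15 min replicate 1 or 2 the fitted log2 difference at that time was 5.17 or 3.11 for Acp2 and 4.92 or 2.96 for GI18622. These fitted values rest on conspecific levels not above background and show only how far the difference moved. With the day as a block the adjusted p of GI17134 at 2 h was 0.411. Groups of 2 arrays are too small for a search for outlying arrays.

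For the 27 transcripts called between mating types over the 3 times, the real split called 32 in a fit of the 12 mated arrays alone. As many were called by 2 of 100 splits, the real one and 1 other, with 1821 for the highest other. The split by extraction day, not among those drawn, called 1525, which points to a structure of the arrays near the days. The real split differs from that by day in 2 arrays. The test therefore argues against chance only for arrays otherwise alike, and cannot exclude a chance overlap with that structure. Day as the whole cause is argued against by 26 of the 27 keeping their direction in both within-day comparisons, although the same arrays served to choose them, and by a median share of the change kept of 1.12 with the day as a block, where 10 stayed called and the median SE grew 1.44 times; a 3' bias is argued against by a median share kept of 0.994 with the probe slope as a covariate, where 14 stayed called and the SE grew 1.14 times. Mismatch of the D. mojavensis probes to D. arizonae RNA would lower a signal, so it was weighed for the 12 lower transcripts. It is argued against for 4 (GI14885, GI14996, GI15007 and GI20849) by an upper 95% bound below 0 for heterospecific minus virgin. That held for 4 with the day as a block and 3, all but GI14885, with median scaling. However, these 4 were chosen by a mean after conspecific mating not above virgin, which favours a level below virgin. The probes of the 12 differed by a median SD of 0.174, under the 75th percentile of 0.499 for 170 time-regulated transcripts of like change. For the other 8, whose mean after conspecific mating lay above virgin, called or not, the median SD was 0.267. That lay between the 0.203 of unselected transcripts and the median of 0.32 of the 170. The 170 are a weak reference, since their change with time cannot be told apart from a 3' bias, which acts unequally on probes. Of the 8, 2 had probes that spread more between mating types than between conspecific and virgin, which decides nothing. For these 8 mismatch may lower part of the signal and cannot be told apart from less RNA. A difference between the species of the males stays open as a biological explanation and was not tested apart from these. All 4 dim arrays were read on day 2 and none was heterospecific, so low raw intensity partly follows mating type. It was not among the explanations weighed here.

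Of transcripts raised over the 3 times, 16 pairs of transcript and mating type, from 13 transcripts, were weighed apart from 11 pairs raised in comparisons at a single time (GI10515 at both 2 h and 6 h) and not in that mean. RNA received from the male is a candidate explanation for the 16, since 13 were lower at 6 h than at 15 min, 5 of 5 after conspecific mating and 8 of 11, under the 80% set for the test, after heterospecific mating, and within a day 5 of 5 and 9 of 11 were. For the 16 as a set, induction in the female that builds up from 15 min is argued against by only 3 pairs being higher at 6 h, and drift of the scale, tested before normalization, which holds the change at a given level near 0, by a median change of 0.0977 for transcripts of like level, beside -1.01 for the pairs. Of the 11 others 8, all after heterospecific mating and called at 2 h or 6 h (GI10243, GI10515, GI16116, GI17784, GI18047, GI19251, GI21109 and GI23861), were higher at 6 h and 3, all after conspecific mating and called at 15 min, were lower, as their choice by time favours, so induction that builds up stays open for the 8 and there was no general decline, with 16 of all 27 lower at 6 h. A fast, short induction in the female would also fall with time and stays open, the 4 Acp transcripts did not pass after conspecific mating, 3 of them were not above background in virgins, and male glands were not analysed here.

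For the 329 transcripts that differed between 15 min and 6 h, the real split called 288 in a fit of the 8 arrays alone. Of 35 splits only 1, the real one, gave as many calls, with 103 for the highest other. This argues against chance for arrays otherwise alike, though 35 splits allow no smaller share. It cannot exclude differences in array quality that fell with time by chance, since these would also set the real split apart. Extraction day as the whole cause is argued against by 327 keeping their direction in both within-day comparisons, with the same limit on the choice of arrays, and by a median share kept of 0.988 with the day as a block, where 61 of them stayed called and the SE grew 1.21 times. A 3' bias cannot be told apart from a change with time, since with the probe slope as a covariate the median share kept was 0.852, the SE grew 1.18 times and 17 of the 329 stayed called. The first principal component followed that slope with r of 0.821, as a quality difference between arrays could give. The 4 dim arrays were also the 4 highest on that component. Low raw intensity was not told apart from the slope for it. For the day, the smaller of the 2 within-group differences on that component was 0.396 and the larger 0.883 of the difference between day means, which does not decide.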

How the results depend on the processing

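The background limit and both filters at it, the fits within a day, without the 4 dim arrays and with the probe slope as a covariate, all results over both mating types at 6 h against 15 min or over the 3 times against virgin, and the Acp tests were chosen after the data were seen. Of 1600 refits of 55 pairs of named transcript and comparison, 1232 stayed past the threshold, 368 kept their direction and lost the call, and 0 reversed. Of 55 pairs, 43 lost the call with the deposited value table, 32 with only the groups compared, 19 with median scaling, 19 without the 4 dim arrays, 12 with array weights, 11 with the extraction day as a block, 11 with the probe slope as a covariate and 10 with no background correction. GI20303 against virgin stayed called at 15 min and 2 h after both matings in every fit run, with log2 changes of 4.81 to 5.73 and 4.43 to 5.31 after conspecific mating and 5.49 to 6.37 and 4.93 to 6.39 after heterospecific mating. Counts of called transcripts moved by over 1.5 times as follows, with the split where the larger direction changed. The cause of these moves was not tested. Fits without the 4 dim arrays kept a lone array in the virgin and in each conspecific group, with the spread taken from the heterospecific groups.

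With a normexp offset of 0, the count was 2 for conspecific against virgin, 6 h, 15 for heterospecific against virgin, 15 min, 16 (11 higher, 5 lower) for heterospecific against conspecific, 15 min and 23 for heterospecific against virgin, mean of 3 times. With no background correction, the count was 5 for heterospecific against conspecific, 15 min, 16 for heterospecific against conspecific, mean of 3 times, 9 for 6 h against 15 min, conspecific and 8 for heterospecific against virgin, mean of 3 times. With median scaling, the count was 5 for conspecific against virgin, 15 min, 2 for conspecific against virgin, 6 h, 6 for heterospecific against virgin, 2 h, 11 for heterospecific against virgin, 6 h, 0 for heterospecific against conspecific, 6 h, 12 for heterospecific against conspecific, mean of 3 times, 0 for 6 h against 15 min, conspecific, 2 for 6 h against 15 min, heterospecific and 11 for 6 h against 15 min, both mating types. With cyclic loess, the count was 6 for heterospecific against virgin, 2 h, 38 (17 higher, 21 lower) for heterospecific against virgin, 6 h, 0 for heterospecific against conspecific, 6 h and 11 for 6 h against 15 min, heterospecific. With the mean of the probes, the count was 8 for conspecific against virgin, 6 h and 32 for 6 h against 15 min, conspecific. With the deposited value table on the log2 scale, the count was 1 for conspecific against virgin, 15 min, 1 for conspecific against virgin, 2 h, 0 for conspecific against virgin, 6 h, 1 for heterospecific against virgin, 15 min, 1 for heterospecific against virgin, 2 h, 1 for heterospecific against virgin, 6 h, 0 for heterospecific against conspecific, 15 min, 0 for heterospecific against conspecific, 2 h, 0 for heterospecific against conspecific, 6 h, 5 for heterospecific against conspecific, mean of 3 times, 0 for 6 h against 15 min, conspecific, 0 for 6 h against 15 min, heterospecific, 1 (1 higher, 0 lower) for 6 h against 15 min, both mating types, 2 for conspecific against virgin, mean of 3 times and 2 for heterospecific against virgin, mean of 3 times. With the 7451 transcripts above the limit on every array, the count was 2 for conspecific against virgin, 15 min, 2 for conspecific against virgin, 2 h, 1 for conspecific against virgin, 6 h, 2 for heterospecific against virgin, 15 min, 5 for heterospecific against virgin, 2 h, 1 for heterospecific against conspecific, 15 min, 1 for heterospecific against conspecific, 2 h, 0 for heterospecific against conspecific, 6 h, 3 (1 higher, 2 lower) for heterospecific against conspecific, mean of 3 times, 27 for 6 h against 15 min, conspecific, 2 for conspecific against virgin, mean of 3 times and 4 for heterospecific against virgin, mean of 3 times. With the 9508 above it in 1 group, the count was 2 for conspecific against virgin, 6 h and 30 for 6 h against 15 min, conspecific. With eBayes trend and robust settings, the count was 2 for conspecific against virgin, 6 h, 18 for heterospecific against virgin, 15 min, 17 (11 higher, 6 lower) for heterospecific against conspecific, 15 min and 23 for heterospecific against virgin, mean of 3 times. With only the groups compared, the count was 1 for conspecific against virgin, 15 min, 1 for conspecific against virgin, 2 h, 0 for conspecific against virgin, 6 h, 1 for heterospecific against virgin, 15 min, 1 for heterospecific against virgin, 2 h, 1 for heterospecific against virgin, 6 h, 0 for heterospecific against conspecific, 15 min, 0 for heterospecific against conspecific, 2 h, 0 for heterospecific against conspecific, 6 h, 0 for 6 h against 15 min, conspecific, 34 (22 higher, 12 lower) for 6 h against 15 min, heterospecific, 165 for 6 h against 15 min, both mating types and 2 for conspecific against virgin, mean of 3 times. With a change of at least 2-fold, the count was 17 for heterospecific against conspecific, mean of 3 times and 141 for 6 h against 15 min, both mating types. With the extraction day as a block, the count was 5 for heterospecific against virgin, 2 h, 7 for heterospecific against virgin, 6 h, 15 (11 higher, 4 lower) for heterospecific against conspecific, 15 min, 10 for heterospecific against conspecific, mean of 3 times, 110 for 6 h against 15 min, conspecific, 80 for 6 h against 15 min, both mating types and 7 for heterospecific against virgin, mean of 3 times. With array weights, the count was 2 for conspecific against virgin, 6 h, 56 for heterospecific against virgin, 6 h, 1 for 6 h against 15 min, conspecific, 81 (42 higher, 39 lower) for 6 h against 15 min, heterospecific and 5 for heterospecific against virgin, mean of 3 times. Without the 4 dim arrays, the count was 3 for conspecific against virgin, 2 h, 138 for conspecific against virgin, 6 h, 3 for heterospecific against virgin, 15 min, 4 for heterospecific against virgin, 2 h, 79 for heterospecific against virgin, 6 h, 5 for heterospecific against conspecific, 15 min, 39 (2 higher, 37 lower) for heterospecific against conspecific, 6 h, 9 (2 higher, 7 lower) for heterospecific against conspecific, mean of 3 times, 48 (30 higher, 18 lower) for 6 h against 15 min, conspecific, 799 (490 higher, 309 lower) for 6 h against 15 min, heterospecific, 824 (519 higher, 305 lower) for 6 h against 15 min, both mating types and 4 for heterospecific against virgin, mean of 3 times. With the probe slope as a covariate, the count was 8 for conspecific against virgin, 2 h, 6 for heterospecific against virgin, 2 h, 2 for heterospecific against conspecific, 6 h, 15 (7 higher, 8 lower) for heterospecific against conspecific, mean of 3 times, 1 for 6 h against 15 min, conspecific and 19 for 6 h against 15 min, both mating types. On day 1 alone, the count was 94 (17 higher, 77 lower) for heterospecific against conspecific, 6 h and 264 (141 higher, 123 lower) for 6 h against 15 min, heterospecific. On day 2 alone, the count was 2 for conspecific against virgin, 15 min, 2 for conspecific against virgin, 2 h, 1 for conspecific against virgin, 6 h, 15 for heterospecific against virgin, 15 min, 0 for 6 h against 15 min, conspecific and 2 for conspecific against virgin, mean of 3 times.

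With the replicate block the count was 2 for conspecific against virgin, 6 h, 9 for heterospecific against conspecific, mean of 3 times, 10 for 6 h against 15 min, conspecific and 180 for 6 h against 15 min, both mating types, and it moved no other count by over 1.5 times. Whether equal replicate numbers share a batch is not known. Over 21 pairs of groups, deviations of same-numbered arrays correlated at -0.63 to 0.512, with 13 pairs below 0.1, which does not decide it.

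Leaving out each array in turn, where a lone array is assumed to vary like the others, gave 6 to 13 for conspecific against virgin, 15 min, 2 to 6 for conspecific against virgin, 2 h, 2 to 30 for conspecific against virgin, 6 h, 4 to 33 for heterospecific against virgin, 15 min, 1 to 326 for heterospecific against virgin, 2 h, 4 to 389 for heterospecific against virgin, 6 h, 3 to 35 for heterospecific against conspecific, 15 min, 0 to 9 for heterospecific against conspecific, 2 h, 0 to 13 for heterospecific against conspecific, 6 h, 8 to 32 for heterospecific against conspecific, mean of 3 times, 0 to 50 for 6 h against 15 min, conspecific, 2 to 32 for 6 h against 15 min, heterospecific, 0 to 16 for mating type by time, 6 h against 15 min, 8 to 722 for 6 h against 15 min, both mating types, 2 to 7 for conspecific against virgin, mean of 3 times and 3 to 291 for heterospecific against virgin, mean of 3 times.

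The correlation of the responses to the 2 matings moved by more than its simulated SD, being 0.521 at 15 min and 0.569 at 6 h with a normexp offset of 0, 0.6 at 2 h and 0.611 at 6 h with no background correction, 0.558 at 15 min, 0.658 at 2 h and 0.493 at 6 h with median scaling. It was 0.511 at 15 min and 0.542 at 2 h with cyclic loess, 0.642 at 2 h with the mean of the probes, 0.56 at 15 min, 0.674 at 2 h and 0.436 at 6 h with the deposited value table on the log2 scale. It was 0.48 at 15 min, 0.552 at 2 h and 0.652 at 6 h with the 7451 transcripts above the limit on every array, 0.496 at 15 min, 0.579 at 2 h and 0.632 at 6 h with the 9508 above it in 1 group, 0.42 at 15 min, 0.424 at 2 h and 0.696 at 6 h with the extraction day as a block. It was 0.565 at 15 min, 0.631 at 2 h and 0.692 at 6 h without the 4 dim arrays, 0.648 at 15 min, 0.708 at 2 h and 0.477 at 6 h with the probe slope as a covariate, 0.418 at 15 min on day 2 alone. Leaving out each array gave 0.212 to 0.832 at 15 min, 0.203 to 0.861 at 2 h and 0.183 to 0.825 at 6 h. The value simulated for unchanged groups was for 2 arrays per group and was not redone for fewer arrays, a block or a covariate.

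The median Acp difference between mating types over the 3 times was 0.57 with a camera adjusted p of 0.0714, and came past the threshold as 0.79 with a normexp offset of 0 (camera adjusted p = 0.0295), 0.64 with the mean of the probes (camera adjusted p = 0.0177), 0.90 with the extraction day as a block (camera adjusted p = 0.0017), 0.71 without the 4 dim arrays (camera adjusted p = 0.0472) and 0.66 with the probe slope as a covariate (camera adjusted p = 0.0171). With an estimated correlation its adjusted p was 0.165, and in these alternatives 0.155 with a normexp offset of 0, 0.16 with the mean of the probes, 0.0385 with the extraction day as a block, 0.222 without the 4 dim arrays and 0.152 with the probe slope as a covariate. For heterospecific against virgin at 15 min the estimated correlation gave an adjusted p of 0.0202, and 0.0985 with median scaling, 0.0748 with the deposited value table on the log2 scale, 0.134 without the 4 dim arrays, 0.0805 on day 2 alone and 0.179 without virgin replicate 1. For heterospecific against conspecific at 15 min it was 0.0512, and 0.0105 to 0.247 over 26 refits. Leaving out each array gave medians of 0.75 to 1.46 for heterospecific against virgin, 15 min, 0.58 to 1.20 for heterospecific against conspecific, 15 min and 0.45 to 0.70 for heterospecific against conspecific, mean of 3 times.

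The alternative with no filter was the same as the fit reported, the slide as a block was not run because each array had a slide of its own, and the preset gene lists could not be refitted because they held no more than 1 transcript. With median scaling the median log2 change of all transcripts was 0.15 for conspecific against virgin at 15 min, 0.16 at 2 h and 0.15 for heterospecific against virgin at 15 min, and -0.13 for heterospecific against conspecific at 2 h, where in the fit reported it was -0.01 to 0.02 over the comparisons. With the deposited value table, which is not normalized, it was -0.22 to 0.19. Of 14519 transcripts, 7451 were above the background limit on every array, and 10 of 24 raised transcripts were not above it in virgins, so that their change has only a lower bound.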

Other observations

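The comparisons described here were added after the data were seen. The 329 transcripts that differed between 15 min and 6 h over both mating types had the same sign of change after both matings, a condition near to that of their choice. For the 143 higher at 6 h, such as GI16419, the median log2 change was 0.983 after conspecific and 0.984 after heterospecific mating, and against virgin the median was -0.0778 at 15 min and 0.91 at 6 h. For the 186 lower ones, such as GI15007, it was -1.04 and -0.795, and against virgin 0.207 at 15 min and -0.66 at 6 h. The dim conspecific 15 min replicate 2 stood alone in its group once replicate 1 was left out. The 329 was 8 without heterospecific 6 h replicate 2 and 722 (397 higher, 325 lower) without conspecific 15 min replicate 1, and without the 4 dim arrays it was 824 (519 higher, 305 lower).

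Averaged over the 3 times, limma called 5 transcripts higher and 1 lower than in virgins after conspecific mating, led by GI20303 at 4.86 (adjusted p = 0.000138) and GI14761 at 4.84 (adjusted p = 1.43e-05). After heterospecific mating it called 11 higher and 4 lower, led by GI20303 at 5.54 (adjusted p = 7.39e-05), while Acp2 was at least 5.11-fold higher (adjusted p = 0.0227) and GI15007 fell by 1.60 (adjusted p = 0.0082). Without virgin replicate 2 the counts were 2 and 3, and without virgin replicate 1 they were 7 and 291 (135 higher, 156 lower), while the adjusted p without virgin replicate 2 was 0.248 for Acp2 and 0.203 for GI15007. After heterospecific mating the count was 9 without either conspecific 15 min array, 6 or 8 without replicate 1 or 2 of heterospecific 2 h and 7 without either heterospecific 6 h array. With median scaling it was 10 higher and 0 lower, with the day as a block 7 and 0, with array weights 5 and 0, and without the 4 dim arrays 4 and 0. GI15007 was then at -1.03 (adjusted p = 0.274) with median scaling, and its adjusted p was 0.184 with the day as a block, 0.0911 with array weights and 0.164 without the dim arrays, where that of Acp2 was 0.206. After conspecific mating the count was 5 higher and 0 lower with median scaling and with cyclic loess. Fits that left out virgin replicate 1 had only the dim virgin replicate 2 as reference.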
